A study of Rattus norvegicus with 16 samples.

How the data were processed

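SRF ChIP-seq and its controls were deposited for primary rat OPC and OL cultures. Per the labels' protocols, OPC proliferated for 6 days, a part of the plates of each preparation was fixed as OPC and the rest after 3 days in differentiation medium, and replicates were independent preparations. Chromatin was sheared in 7 cycles, immunoprecipitated with an antibody against SRF or with IgG, amplified in 12 PCR cycles without size selection, and sequenced as single reads of 75 bp. The submitters' processing notes name Trim Galore, BWA, MACS2, HOMER, deepTools and the build Rnor_6.0; the order of steps and the treatment of duplicate reads and of reads with several matches before peak calling are not given in the sources used here.

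Per the file headers, the authors called peaks with MACS 2.2.7.1 in each library against its input, at a q-value of 0.05 and an effective genome size of 2000000000, keeping all duplicates that reached that step; both IgG libraries were called against the input of replicate 1 of their stage. The deposited peak tables give each peak's pileup signal, its fold enrichment ratio over the local input background and the −log10 of its p and q; these are the authors' values and were used only to describe or filter peaks within a library. The fragment length that MACS estimated was 71 to 86 bp in 7 of the 9 immunoprecipitated libraries, close to the read length, and 296 and 298 bp in OL replicate 2 and the IgG library of OL. The deposited count tables hold whole read counts, not normalized, over the authors' consensus regions (848 for SRF, 126 for IgG), made with featureCounts 2.0.1 at a minimum overlap of 0.2 of the read, per the file headers. Gene names, distances to the nearest TSS and annotations are those of the deposited HOMER tables, and coordinates are in Rnor_6.0, counted from 1. Library depth is the tag total in the deposited peak table headers. The 7 input libraries were not analysed here beyond their use by MACS.

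A consensus region counted as called in a library when it overlapped one of its peaks by at least 1 bp. Reproducible sites needed calls in at least 2 of the 7 SRF libraries and none in an IgG library. Regions with at least 10 reads in at least 3 libraries (557 of 848) entered edgeR 4.0.16 (R 4.3.3) with TMM scaling over the regions and the quasi-likelihood test of OL against OPC, and p-values were adjusted by Benjamini-Hochberg. Normalised read counts are reads divided by the TMM-scaled library size relative to its mean over the 7 libraries. They describe a region relative to the other regions, and a change common to all regions is removed. Scaled to all tags instead, the median region had a log2 fold change of -0.35. On counts simulated for this comparison with 521 regions in the test, the fit recovered 6 of 64 regions changed 1.5-fold, 38 of 62 changed 2-fold and 55 of 61 changed 4-fold, and passed 4 of 334 unchanged ones. These counts were drawn independently for each region from its fitted spread, in proportion to library size and without an effect of preparation. They therefore do not cover reads that fail to follow depth, or the fit with the replicate number as a block.

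Gene lists, tests, the rule for the named genes and the alternatives were fixed before the data were examined, except where an alternative is said to be added later. The 7 lists (362 gene names) cover actin cytoskeleton and adhesion, immediate early and growth factor response, SRF and its cofactors, myelin and oligodendrocyte differentiation, OPC identity and proliferation, markers of other brain cell types, and translation and housekeeping for comparison. A list gene was bound when a reproducible site lay within 10 kb of its TSS as the nearest one, and was compared with all 47286 gene symbols of the RefSeq table of assembly GRCr8 by Fisher's exact test. That table was used for names only, and 325 of 368 gene names with a site (88.3%) matched it. List shifts were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, for lists with at least 3 tested regions. The plan also named fry of the same package, which tests a list without reference to other regions. Single values per library were compared by exact permutation tests with scipy 1.17.1. The named regions are up to 8 sites of bound genes per list, the 12 sites called in the most libraries, up to 10 regions per direction past the threshold or otherwise the 5 smallest p, and up to 5 sites called in only 1 stage, with ties set by mean scaled log2 reads.

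Because each preparation was divided between the stages, per the labels' protocols, replicate numbers 1, 2 and 4 were taken to pair OPC with OL, and OPC replicate 3 has no partner. The deviations of same-numbered libraries from their group means correlated at 0.09, 0.27 and 0.16 for numbers 1, 2 and 4 across regions, and those of OPC replicate 4 with OL replicate 1 at 0.28, so the correlations do not single out the same-numbered libraries and the pairing rests on the labels. The numbers are those of the sample titles. The OL library titled replicate 4 carries the number 3 in its library name, so its partner could be OPC replicate 3 (correlation 0.07) instead of OPC replicate 4, and every blocked value rests on the titles. The fit with the number as a block is an alternative, and a fit that pairs OL replicate 4 with OPC replicate 3 was added later. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 1.25 to 4.15). Alternatives covered DESeq2 1.42.0, other scalings, no filter on low counts, the block, stricter peaks, other overlap and distance limits, and each library left out. A search for the sequence motif that SRF binds was planned and not run, since no genome sequence was used here.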

Results

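The transcription factor SRF (serum response factor, which binds DNA with cofactors of the MRTF and ternary complex factor families) was mapped by chromatin immunoprecipitation and sequencing in primary rat cells at 2 stages of the oligodendrocyte lineage. Oligodendrocyte precursor cells (OPC) were isolated by immunopanning, in which cells are captured on antibody-coated dishes, and grown in proliferation medium. One part of each preparation was fixed as OPC, and the other was fixed as oligodendrocytes (OL) on day 3 of differentiation. The series holds 16 libraries, namely 4 SRF libraries from OPC (replicates 1 to 4), 3 from OL (replicates 1, 2 and 4), an IgG control from each stage and 7 input libraries. The question, as the series title frames it, is which genes SRF binds in these cells, with the cytoskeleton in view, and the paired stages ask how binding differs between OPC and OL.

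Depth differed between the stages. The OPC libraries held 12401853, 20303444, 11713315 and 9054483 tags (replicates 1 to 4), whereas the OL libraries held 12103611, 2394854 and 3363937 (replicates 1, 2 and 4). The IgG library of OPC held 11308414 tags and that of OL 1551203. The authors' consensus over the SRF libraries comprised 848 regions covering 181 kb, with a median count of 14.5 reads per region and library.

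SRF reads gathered at promoters, among them those of immediate early and actin genes. A consensus region with a peak in at least 2 of the 7 SRF libraries and in neither IgG library was taken as a reproducible site, and 448 regions met this. Of these, 313 (69.9%, exact 95% interval 65.4 to 74.1%) lay within 1 kb of an annotated transcription start site (TSS), against 5 of 126 IgG regions (3.97%, interval 1.30 to 9.02%; Fisher's exact test, two-sided, p = 1.67e-44). The annotation placed 295 sites in promoters, 82 between genes, 35 in introns, 21 at transcript ends and 15 in exons, while 115 of the 126 IgG regions lay between genes. Of the 848 regions, 372 were called in 1 library, 256 of them in OPC replicate 4 alone, and 34 overlapped an IgG peak. The intervals cover counting error only.

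The sites called most widely and with the most reads were mostly promoters, that of Egr1 among them. Peaks were called in all 7 libraries at 30 sites. The highest normalised read count was at Gsk3a, which encodes a glycogen synthase kinase (chromosome 1, 82108053 to 82109197, promoter, 422 bp upstream of the TSS), at 315 ± 4.86 in OPC (SD, n = 4) and 407 ± 53.4 in OL (SD, n = 3). Egr1, a zinc finger transcription factor induced within minutes of stimulation, had its site in the promoter (chromosome 18, 27656864 to 27657669), with 162 ± 12.1 and 258 ± 88.0. Fbxl19 (chromosome 1, 199194107 to 199195277, between genes, 1367 bp upstream of the TSS) had 162 ± 7.88 and 264 ± 32.4. The promoter sites of Banp, Prcc, LOC100911959, Ncln, Rnf44, Mmachc, Maf1 and Fam168a and an exon site of Ccdc90b completed the 12 sites named for calls in the most libraries, with OPC means from 90.4 at Fam168a to 182 at Banp. Between OL and OPC 0 of these 12 sites passed by edgeR and 1, Fbxl19, by DESeq2, with 3 at an unadjusted edgeR p below 0.05. Of all 30 sites 0 passed by edgeR and 5 by DESeq2, with 14 at an unadjusted edgeR p below 0.05, all higher in OL. A call in every library, the shallow OL libraries included, selects sites with many OL reads, so this direction is not independent of the choice of sites.

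Immediate early genes were the list with the largest bound share. A reproducible site lay within 10 kb of the TSS of 9 of 62 genes of the immediate early and growth factor response list (14.5%), against 0.669% of other genes (Fisher's exact test, two-sided, odds ratio 25.2, adjusted p = 3.16e-09 over 7 lists). Against named protein-coding genes alone, of which 1.51% were bound, the adjusted p was 3.10e-06. They were Egr1, Egr2, Egr3, Fos, Fosb, Junb, Nr4a1, Dusp5 and Homer1, most of which encode transcription factors, while Dusp5 encodes a phosphatase of ERK and Homer1 a scaffold protein. The sites of Egr2 (chromosome 20, 22458751 to 22459300, at the TSS) and Egr3 (chromosome 15, 51754294 to 51754747, 2216 bp upstream of the TSS) were called in all 7 libraries, as was that of Egr1. Sites of Dusp5, Junb, Fosb and Homer1 were each called in 5. The site of Dusp5 (chromosome 1, 274245001 to 274245238, promoter) had 29.6 ± 7.76 normalised reads in OPC and 39.6 ± 4.43 in OL, and that of Fosb (chromosome 1, 80221687 to 80222124, promoter) had 26.8 ± 6.46 and 47.2 ± 38.4. The site of Junb (chromosome 19, 26092560 to 26092839) lay 2057 bp downstream of its TSS at the transcript's end, and a second site of Egr3 lay in its promoter. Another 4 genes of the list (Arc, Egr4, Fosl1 and Nr4a3) had a region called in 1 library.

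Actin genes were bound as well. Of 100 genes of the actin cytoskeleton and adhesion list, 7 had a reproducible site within 10 kb (7.00%, against 0.674% of other genes; Fisher's exact test, odds ratio 11.1, adjusted p = 2.20e-05). Against named protein-coding genes, of which 1.52% were bound, the adjusted p was 0.00323. They were Actb and Actg1, which encode the cytoplasmic actins, Vcl (vinculin), Wdr1 (a partner of cofilin in filament disassembly), Cnn2 (a calponin), Capzb (an actin capping subunit) and Fermt2 (kindlin-2, an integrin activator). Actb carried a site called in all 7 libraries 806 bp upstream of its TSS (chromosome 12, 13715575 to 13716005, promoter) and another called in 6 (13716462 to 13716880). Actg1 carried a site 2211 bp upstream (chromosome 10, 109522913 to 109523201, between genes, called in 5 libraries) and one in its promoter (109521361 to 109521448, called in 2). The promoter sites of Wdr1 and Cnn2 were called in 4 libraries each, that of Vcl in 3 and that of Capzb in 2. Cap1, Flna, Tpm4 and Vim had a region called in 1 library.

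Srf itself was bound, and lineage genes were not among the bound genes. The promoter site of Srf (chromosome 9, 16737468 to 16737736, 40 bp upstream of the TSS) was called in 4 libraries, with 19.0 ± 7.00 normalised reads in OPC and 30.9 ± 21.3 in OL. It was the only bound gene of the 15 in the list of SRF and its cofactors (adjusted p = 0.229, Fisher's exact test). No reproducible site lay within 10 kb of any of 53 genes of the myelin and oligodendrocyte differentiation list, 44 of OPC identity and proliferation or 37 markers of other brain cell types (adjusted p = 1 for each, Fisher's exact test). Of other genes 0.688% were bound, and with lists of this length 0 bound genes is not a detectable difference from that share. In the translation and housekeeping comparison list 1 of 45 genes was bound, Eef1a1, a translation elongation factor (adjusted p = 0.467, Fisher's exact test). IgG regions lay within 10 kb of the TSS of 1 matched gene, so they give no comparison for the lists.

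The share of tags in SRF regions varied between the OPC libraries, and the number of peaks varied within both stages. Tags in consensus regions made up 0.226 ± 0.110% of all tags in OPC (SD, n = 4) and 0.206 ± 0.0166% in OL (SD, n = 3; exact permutation test, two-sided, p = 0.914, where the smallest p possible with 35 splits is 0.0571, so that no difference could have passed 0.05). OPC replicate 4 had the largest share (0.379%) and OPC replicate 2 the smallest (0.116%), and without OPC replicate 4 the difference of means turned to 0.0308 percentage points in favour of OL. The number of peaks was 440 ± 201 per OPC library (SD, n = 4) and 218 ± 199 per OL library (SD, n = 3; exact permutation test, two-sided, p = 0.229, with the same smallest p). At about equal depth, OL replicate 1 had 436 peaks and OPC replicate 1 had 432, and the shallow OL replicates 2 and 4 had 47 and 172. The IgG libraries had 117 peaks in OPC and 24 in OL.

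**Figure D1:**
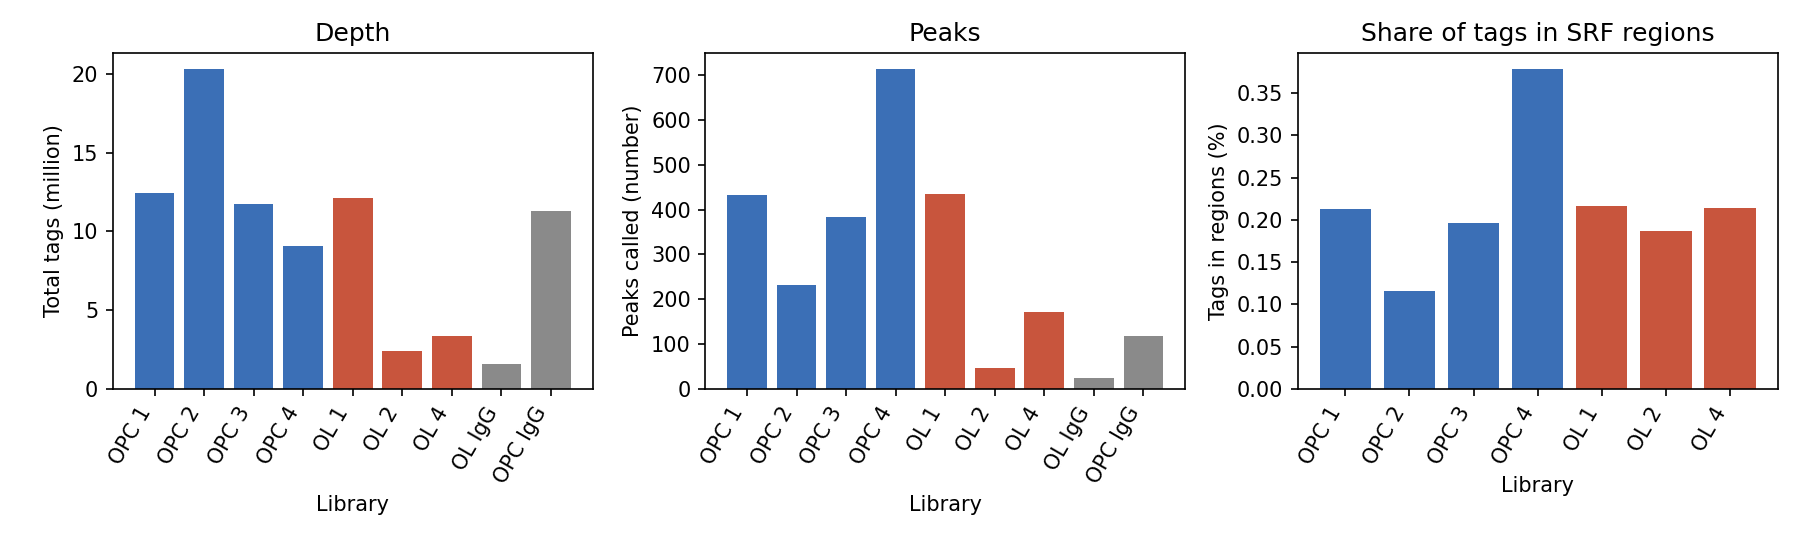
Total tags, number of peaks and percent of tags in the SRF consensus regions for each library, 1 bar per library, with OPC in blue, OL in red and IgG in grey. OL replicates 2 and 4 hold 2394854 and 3363937 tags and 47 and 172 peaks, while their shares of tags in regions, 0.187% and 0.214%, lie within the range of the OPC libraries.

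In the fit that ignores the pairing by preparation, a small set of regions differed between the stages, most of it lower in OL. Of 557 regions tested, 12 passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 10 of them lower and 2 higher in OL. Of the 10 lower regions 6 lay within 10 kb of the TSS of a small nuclear or nucleolar RNA gene, and the smallest p was that near SNORA76 (log2 fold change -2.20 ± 0.31 SE, edgeR adjusted p = 0.0139). The 2 higher regions were the upstream site of Actg1 and a region between genes 39659 bp upstream of Klf7, a Krüppel-like transcription factor. None of the 12 overlapped an IgG peak. With the replicate number as a block 0 regions passed. The direction also varied with the fit, with 29 regions higher and 13 lower in OL by DESeq2.

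Upstream of Actg1 the normalised read count was 19.1 ± 1.29 in OPC (SD, n = 4) and 57.0 ± 26.1 in OL (SD, n = 3), a log2 fold change of 1.46 ± 0.30 (SE) with an edgeR adjusted p of 0.0364. At the Klf7 region (chromosome 9, 70827466 to 70827679), called in 1 library of each stage, the counts were 10.6 ± 4.48 and 35.8 ± 6.03 (log2 fold change 1.72 ± 0.35, edgeR adjusted p = 0.0355). Every OL library exceeded every OPC library at both. Before scaling, these higher regions rest on few reads in the shallow OL libraries. OL replicates 1, 2 and 4 held 45, 8 and 25 reads upstream of Actg1 and 42, 7 and 9 at the Klf7 region. The next smallest p in this direction did not pass. They belonged to a pair of regions with an IgG peak on chromosomes 1 and 13, far from any TSS (log2 fold changes 2.11 and 1.98, edgeR adjusted p = 0.0668 and 0.0699), and to the upstream site of Actb, with 51.7 ± 6.45 normalised reads in OPC and 96.4 ± 27.2 in OL (log2 fold change 0.82 ± 0.21, edgeR adjusted p = 0.0699).

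Among the lower regions, that near SNORA76 (chromosome 10, 94698114 to 94698811, exon) fell from 36.3 ± 3.83 normalised reads in OPC (SD, n = 4) to 8.77 ± 4.36 in OL (SD, n = 3). That near SNORD81 (chromosome 13, 78856789 to 78857538, transcript end) fell from 37.7 ± 5.60 to 10.9 ± 3.54, and the intronic one near SNORA24 (chromosome 2, 227716812 to 227718130) from 63.0 ± 13.5 to 25.4 ± 10.9. Regions 718 to 824 bp downstream of the TSS of a U2 gene (chromosome 9, 79597529 to 79597843) and of a pair of U5 genes (chromosome 8, 70701296 to 70701581, and chromosome 5, 136058131 to 136058535) fell by 1.82, 1.38 and 1.60 on the log2 scale. Genes of U2 and U5, RNAs of the spliceosome, have near-identical copies in the genome, and reads from such copies can be misplaced, so these positions are uncertain. The remaining lower regions lay at the transcript end of Fam53c (log2 fold change -1.33 ± 0.22), at a transcript end near Cacng7, a calcium channel subunit gene (-1.02 ± 0.22), in the promoter of RGD1562987 (-2.39 ± 0.48) and 13768 bp upstream of Fuk, a fucokinase gene (-0.92 ± 0.20). At Fam53c (chromosome 18, 27558188 to 27558685) the count fell from 51.4 ± 6.30 to 21.4 ± 5.35. Before scaling, the OL values at many lower regions rest on few reads. In OL replicates 1, 2 and 4 there were 8, 1 and 4 reads near SNORA76, 7, 1 and 2 near the U2 gene and 17, 2 and 2 near SNORD81. The region near Fuk held 50, 10 and 10. The region of RGD1562987 held 2, 1 and 1, was called in 1 library and is not a reproducible site.

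The count of 12 depended on the fit and on single libraries. With the replicate number as a block, which pairs OPC and OL of the same preparation, edgeR passed 0 regions (smallest adjusted p = 0.0774, 106 regions at an unadjusted p below 0.05), and scaled to all tags it also passed 0 (40 at an unadjusted p below 0.05), while DESeq2 passed 42, of which 29 were higher and 13 lower in OL and 13 overlapped an IgG peak. It was 4 without OPC replicate 1, 4 without OPC replicate 2, 1 without OPC replicate 4, 31 without OL replicate 1 (28 higher and 3 lower, 15 with an IgG peak), 7 without OL replicate 2 and 6 without OL replicate 4, and the sign of the 12 main calls was the same in each of these fits. Without both shallow OL libraries it was 1, in a fit where OL replicate 1 alone remained, was assumed to vary like OPC and gave no spread of its own.

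**Figure D2:**
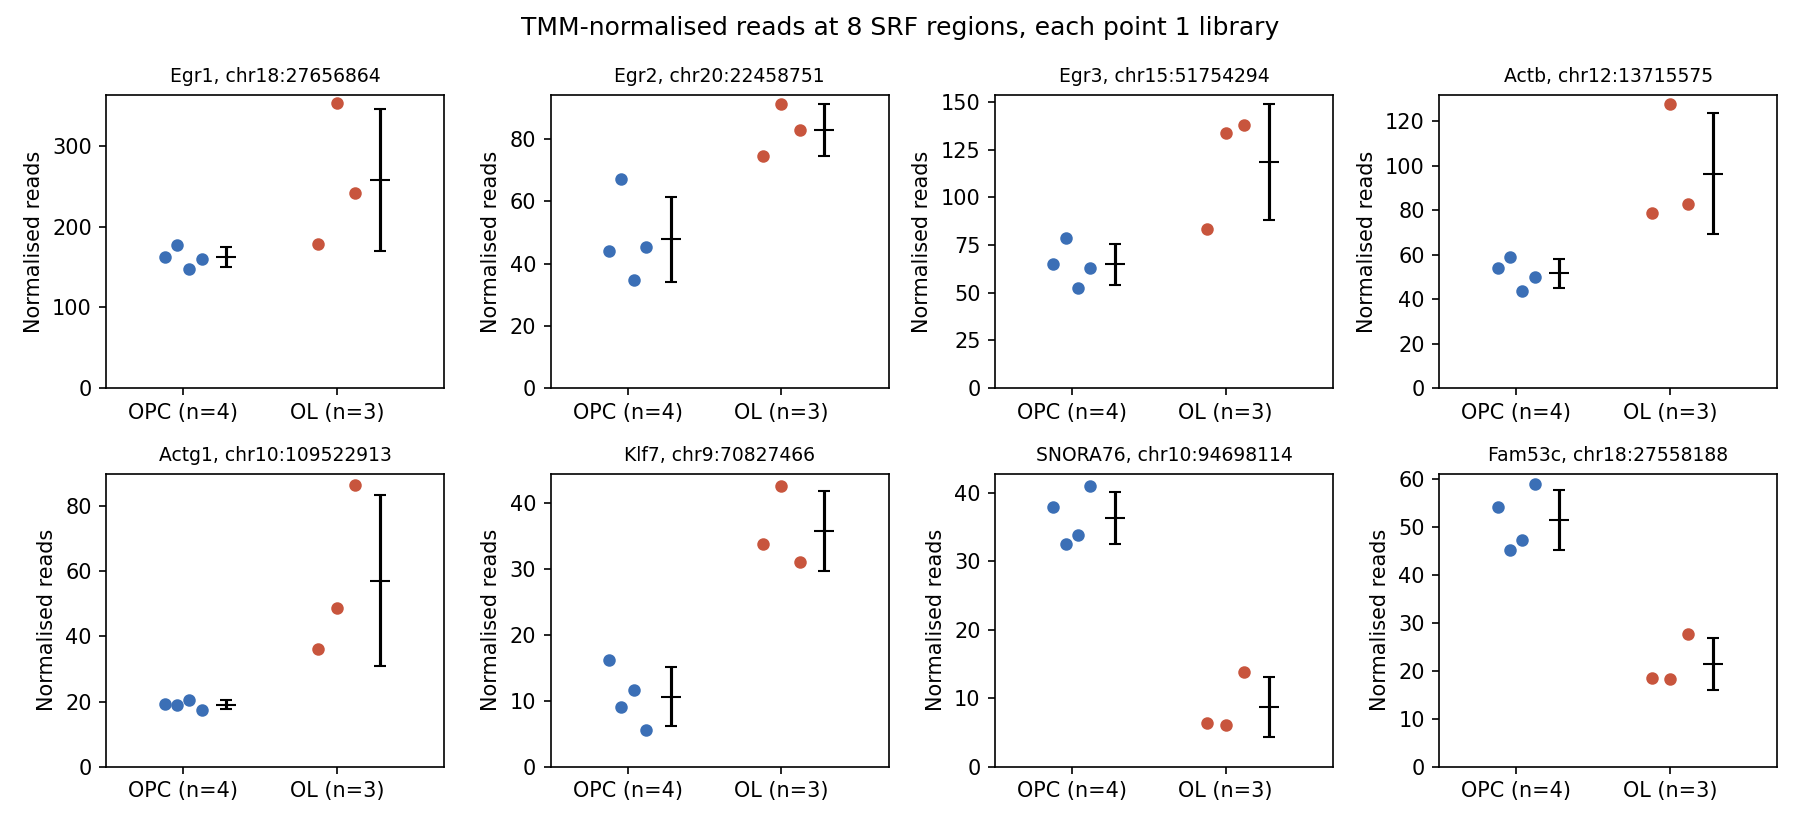
TMM-normalised reads at 8 named regions (chromosome and start in each title), 1 point per library, with the mean and SD in black beside the points. OL libraries lie above the OPC libraries at Actg1 and Klf7, and below them at SNORA76 and Fam53c, the regions of this set that passed the test. OL libraries also lie above the OPC libraries at Egr1, Egr2, Egr3 and Actb, which did not pass. At Egr1 the gap is narrow, with 179 in OL replicate 1 and 177 in OPC replicate 2. The 8 regions were picked for display, and 20.5% of all tested regions had OL libraries all above or all below the OPC libraries.

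Regions of the actin list had more reads in OL relative to other regions. Of 7 tested regions 6 had a positive log2 fold change, with a median of 0.63 against -0.01 for all others (camera with a preset correlation, p = 0.00158, and p = 0.0308 with an estimated correlation). By edgeR 1 region, that upstream of Actg1, passed over all regions (2 by DESeq2) and 3 when adjusted over the list alone. Beyond Actg1 and Actb, the promoter of Wdr1 (chromosome 14, 76989677 to 76989886) had 15.3 ± 3.36 normalised reads in OPC (SD, n = 4) and 29.4 ± 5.69 in OL (SD, n = 3), with a log2 fold change of 0.83 ± 0.28 and an edgeR adjusted p of 0.111. Vcl stood at 12.4 ± 3.73 and 10.0 ± 3.79 (log2 fold change -0.02 ± 0.37). The second site of Actb had a log2 fold change of 0.42 ± 0.23 and Cnn2 of 0.31 ± 0.43. Capzb, whose value is the list's median, had 0.63 ± 0.46 (edgeR adjusted p = 0.506). The promoter site of Actg1 and the site of Fermt2 were not among the tested regions. OL replicate 2 held 5 reads at Wdr1, 7 at Cnn2 and 1 each at Capzb and Vcl. With the replicate block 0 regions passed over all regions and 2 when adjusted over the list alone, and the list's camera p was 0.00425, and p = 0.164 with an estimated correlation. The p with an estimated correlation was also 0.239 when scaled to all tags, 0.0682 for regions within 1 kb of the TSS, and 0.0524, 0.0936 and 0.0979 without OPC replicate 3, OL replicate 1 or OL replicate 4.

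Regions of the immediate early list had positive log2 fold changes at 10 of 11 tested regions, with a median of 0.32 against -0.02 for all others. The set test passed with the preset correlation (camera, p = 0.00702) and not with an estimated one (p = 0.298). Over all regions 0 of the 11 passed by edgeR and 0 by DESeq2, with 3 at an unadjusted edgeR p below 0.05, and 2 passed by edgeR when adjusted over the list alone, against 0 with the replicate block. Over all regions 3 of 10 passed by edgeR when only reproducible sites were tested, and 1 of 10 without OL replicate 1. Egr2 had 47.8 ± 13.6 normalised reads in OPC (SD, n = 4) and 82.9 ± 8.30 in OL (SD, n = 3), with a log2 fold change of 0.76 ± 0.23 and an edgeR adjusted p of 0.107. Egr3 had 64.8 ± 10.8 and 118 ± 30.4 (log2 fold change 0.81 ± 0.24, edgeR adjusted p = 0.0944), and Egr1 a log2 fold change of 0.63 ± 0.27 (edgeR adjusted p = 0.203). Junb had a log2 fold change of 0.06 ± 0.23. The camera p was 0.0578 without OPC replicate 3, 0.0711 without OL replicate 2 and 0.0986 without both shallow OL libraries, where 1 OL library remained, the spread came from OPC alone and the median was 0.15. Fewer than 3 regions were tested for the lists of SRF and its cofactors, myelin and OPC identity, which were not tested as sets; the site of Srf had a log2 fold change of 0.47 ± 0.41 (edgeR adjusted p = 0.607). Eef1a1 of the comparison list had a log2 fold change of -1.40 ± 0.34 at a region 3752 bp downstream of its TSS (edgeR adjusted p = 0.0659).

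**Figure D3:**
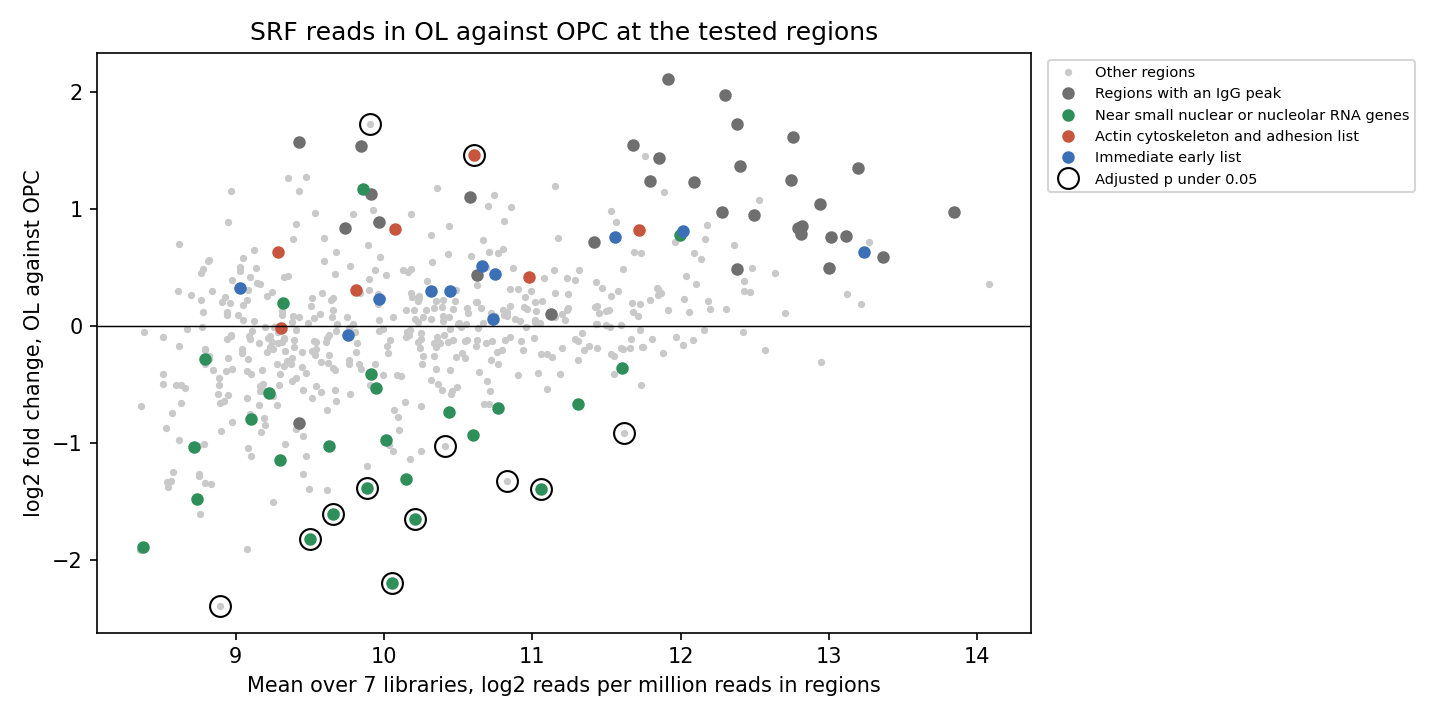
Log2 fold change of OL against OPC for the 557 tested regions, plotted against the mean log2 read abundance over the 7 libraries (scaled to all reads in regions), with 4 sets of regions in colour and the 12 regions past the threshold circled. Regions with an IgG peak lie above 0 in 32 of 33 cases, and regions near small nuclear or nucleolar RNA genes, a set noticed in the data, below 0 in 23 of 26.

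Most reproducible sites were called at both stages. Of the 448 reproducible sites 355 (79.2%) were called in at least 1 library of each stage, 93 (20.8%) were called in at least 2 OPC libraries and no OL library, and 0 were called in at least 2 OL libraries and no OPC library. With 47 and 172 peaks in OL replicates 2 and 4, the last class could hardly be filled, so these counts do not compare the stages. The 5 OPC-only sites with the most reads lay near U6, SNORA24, U1 and SNORD81 and 27805 bp upstream of LOC100911156. At those near U6 (chromosome 4, 6879519 to 6879611) and LOC100911156 (chromosome 20, 48786654 to 48786766) the mean normalised read count was higher in OL (125 ± 70.5 and 120 ± 70.5, SD, n = 3) than in OPC (66.2 ± 18.3 and 65.6 ± 16.7, SD, n = 4), and neither difference passed (edgeR adjusted p = 0.283 and 0.323). OL replicate 1 stood at 53.8 and 54.6, within the OPC range at both. The higher means came from the shallow OL replicates 2 and 4, with 195 and 128 near U6 and 195 and 110 near LOC100911156. The site near U1 (chromosome 2, 198528493 to 198529116, transcript end) had 40.6 ± 6.42 and 19.6 ± 3.23 (log2 fold change -0.93 ± 0.23, edgeR adjusted p = 0.0668).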

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

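The tests of deviating libraries, of read counts against depth, of the shallow libraries and of other splits were chosen after their results had been seen; the tests of background reads, of shared reads and of abundance were written before, that of abundance once fold changes had been plotted against it. Among 49 values tested for a library that stands apart in OPC, 1 did, where chance flags about 1 in 20. At Prcc, OPC replicate 2 had 186 normalised reads and the other OPC libraries between 159 and 163, a gap of 0.877 of the range.

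The 12 regions past the threshold were set against the other splits of the 7 libraries into 4 and 3. Of the 35 splits, 1, the real one, gave 12 or more regions, and the highest of the others gave 2. This share lies under 0.05 only where the pairing by preparation is ignored, so a chance split is not excluded for the paired design. Among the 8 splits that part 3 pairs of same-numbered libraries, as the real one does, the highest other also gave 2, and 8 splits are too few for a share under 0.05. With the replicate block 0 regions passed by edgeR (106 at an unadjusted p below 0.05).

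Regions near small nuclear and nucleolar RNA genes were lower in OL at 23 of 26 tested regions (median log2 fold change -0.95), a set formed after its members had been seen among the lower regions, so that no p is given for it. The reads expected from depth and region length, at an even rate over the genome, were subtracted. The set's median then lay -0.99 from that of other regions (bootstrap interval -1.63 to -0.75), against -0.82 before. The subtracted reads were few, at 1120 of 26362 reads in all regions in OPC replicate 1 and 216 of 4472 in OL replicate 2. So small an even floor could hardly have closed the gap, and no conclusion on background is drawn. The intervals in this paragraph resample regions, which share the same 7 libraries, and do not measure spread between libraries. Local background at these regions was not measured, since the input libraries were not analysed, and it stays open. No single library carries the pattern, because the median closest to 0 with 1 library left out was -0.79 (-0.81 without both shallow OL libraries). Reads shared between near-identical snRNA genes cannot be told apart from a stage difference, since the regions near snoRNA genes, which would lack them, number 5 and lay -1.37 from other regions with a bootstrap interval of -2.17 to 1.19. A difference between precursors and differentiated cells in SRF binding or in chromatin that is open at heavily transcribed small RNA genes may underlie it, as a hypothesis that was not tested.

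Regions with an IgG peak had higher normalised reads in OL at 32 of 33 (median log2 fold change 0.97, camera with an estimated correlation p = 0.0971). Reads there followed depth only in part, with a median slope of log2 reads on log2 total tags of 0.52, against 1.06 in the other regions. At the region on chromosome 1 from 180644646 to 180645170, the libraries held 57, 57, 56 and 61 reads in OPC and 61, 61 and 62 in OL, although depth ranged from 2394854 to 20303444 tags. Without both shallow OL libraries, which leaves 1, the median was 0.05. This is consistent with a ceiling on reads per position, such as removal of duplicates in repeats would give, and leaves the difference between stages at these regions open to depth rather than biology.

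The actin list was higher in OL (median log2 fold change 0.63 over 7 regions). After subtraction of a background spread evenly over the genome, the list lay 0.62 above other regions (bootstrap interval 0.48 to 1.21). The interval resamples regions, a pair of them neighbours at Actb, and does not measure spread between the libraries they share. The subtracted background was a small part of the reads in regions. No conclusion on background is therefore drawn, and local background was not measured. Fold change rose with abundance across the 524 regions without an IgG peak (Spearman's rho 0.337, across regions that are not independent replicates), yet the list's median of 0.63 exceeded the range of -0.42 to 0.29 that holds 95% of medians of lists matched on abundance. With OL replicate 1 as the only OL library the median was 0.59 and the p with an estimated correlation 0.139, so a part played by both shallow libraries cannot be told apart from a stage difference on 1 remaining library. More SRF at actin genes in OL relative to other sites may be the biological reading, as a hypothesis only.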

How the results depend on the processing

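The settings without regions that have an IgG peak, without regions near small RNA genes and without both shallow OL libraries, the pairing of OL replicate 4 with OPC replicate 3 and the protein-coding background were added after seeing the data, as were, for the list shifts, median-of-ratios scaling, sums over regions, no filter, the block with library totals and reproducible sites only; the others were planned. The count of 12 regions was 42 with DESeq2, 24 with sums over regions as library size (5 higher, 19 lower in OL), 22 without a filter on low counts, 35 among reproducible sites only (17 higher, 18 lower) and 24 without regions that have an IgG peak (7 higher, 17 lower); the 12 (11 of them tested in reproducible sites) passed in each of these. It was 0 under library totals without TMM, 0 under the replicate block, 0 under the replicate block with library totals (53 at an unadjusted edgeR p below 0.05), 0 without regions near small RNA genes (106, with a smallest adjusted p of 0.0564) and 1 without both shallow OL libraries, where 1 OL library remains. Leaving out 1 library gave 1 to 31 regions. The block spends degrees of freedom and OPC replicate 3 then carries no information on the difference. It also took the regions passing over the list alone from 3 to 2 (actin) and from 2 to 0 (immediate early), ended the call at Actg1 (edgeR adjusted p = 0.0774) with the others of the 12 and ended the actin list's call with an estimated correlation; both lists stayed past the threshold with the preset correlation. With OL replicate 4 paired to OPC replicate 3 the replicate block passed 0 regions (105 at an unadjusted edgeR p below 0.05), and the actin list had p = 0.111 with an estimated correlation. For the losses under the block and for the others the cause was not tested. The difference in the share of tags ran from -0.0568 to 0.0308 percentage points as single libraries were left out, turning positive without OPC replicate 4 (0.0308). Reproducible sites numbered 814 with calls in at least 1 library and between 342 and 476 under the other settings, and the share within 1 kb of a TSS stayed between 61.2 and 72.5%. For the immediate early list, the median of 0.32 lost its call with an estimated correlation, and that of 0.15 without both shallow OL libraries; single libraries left out gave medians of 0.18 to 0.59, where the call was lost without OPC replicate 3 and without OL replicate 2, for a cause that was not tested. The actin list's median ran from 0.20 (library totals, where other regions lay at -0.36) to 0.84, past the threshold with the preset correlation in each setting. With an estimated correlation its call (p = 0.0308) was lost under library totals (p = 0.239), the block (p = 0.164), the block with library totals (p = 0.393), 1 kb to the TSS (p = 0.0682), without OPC replicate 3, OL replicate 1 or OL replicate 4 (p = 0.0524 to 0.0979) and without both shallow OL libraries (p = 0.139). The enrichments of both lists passed in every setting, with bound shares of 5 to 11% (actin) and 9.68 to 21.0% (immediate early), and the other 5 lists passed in none. The search for the SRF motif was not run, because no genome sequence was used. OL replicates 2 and 4, with 47 and 172 peaks, limit what can be seen at weak sites in OL.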

Other observations

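The tests here were chosen after the data had been seen. The regions that the small RNA genes contributed were mostly past the gene rather than at its start. Repeated U2 genes on chromosomes 9 and 10 and U1 genes on chromosome 2 accounted for many of the 26, and several lay between 695 and 1004 bp downstream of the annotated start. Transcript ends of other genes, a set of 9 regions also noticed in the data, had a median log2 fold change of 0.10 and a mean of -0.14, with those at Fam53c and Cacng7 among them.

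The immediate early list, with a median log2 fold change of 0.32, lay within the range that holds 95% of medians of lists matched on abundance (-0.23 to 0.33). Of the 557 tested regions 114 (20.5%) had OL libraries all above or all below the OPC libraries. Ties aside, the average of this share over all 35 splits of the libraries is 5.71%. Regions are not independent replicates, so a single split can lie far from that average, and the share was not computed for other splits. The comparison also ignores the pairing by preparation, and with the replicate block 0 regions passed by edgeR (106 at an unadjusted p below 0.05).

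Of the 34 SRF regions with an IgG peak, 15 lay on chromosome 1 and 6 on chromosome 13, most of them between genes. The only one with a library at 0 reads lay on chromosome 20 (27461519 to 27461659), 90760 bp from the nearest annotated TSS, that of Rwdd1. There OPC replicate 2 had 124 reads and OL replicate 4 had 0.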
